A study of Drosophila melanogaster with 4 samples.

How the data were processed

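Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 dimethylated at lysine 27 (H3K27me2) in nuclei from heads of adult Oregon-R flies, a wild-type laboratory strain of Drosophila melanogaster. Per the labels' protocols, heads were collected by sieving, the tissue was fixed with formaldehyde, nuclei were lysed and sonicated, and the chromatin was precipitated with the antibody Ab24684. The series held 4 samples, namely 2 ChIP replicates and 2 inputs, and each input was assigned by its label to the ChIP replicate of the same number. The labels do not say whether the replicates came from separate collections of flies, so the spread between them may be technical.

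The analysis started from 3 deposited lists of enriched regions, 1 per ChIP replicate and 1 for the series. The inputs have no list of their own and enter through the authors' region calls and, as the scores are read here, through the scores. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold and the way the replicates were combined for the series' list are not given in the sources used here. Per the file headers, coordinates are those of FlyBase release 5, and each line is a region of significant enrichment with a start, an end and a score. The score deposited by the authors for each region has no stated scale. It was used to describe, rank or filter regions within 1 list, and to correlate overlapping regions of the replicates.

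The scale of the score was therefore examined from its values. Each score was compared with log2 of a ratio of whole numbers, allowing a relative difference of 1e-12 and denominators up to 20000. After addition of 1 constant per list, 100% of the scores in each list were such a log2 ratio. For the distinct steps from the most frequent score, the share that was a ratio of whole numbers was 100% in both replicates and 99.97% in the series' list on the log2 scale. It was at most 0.0704% on a natural-log scale, 0.106% on a log10 scale and 0.106% on a linear scale. The constant of each list was chosen so that the terms were divisible by small primes about as often as whole numbers in lowest terms are. Their divisibility by 2, 3, 5 and 7 (for 2, 33.3% and 33.5% in replicate 1, where 33.3% is the expectation) follows from that choice. It is no separate support for reading the terms as read numbers. The upper term was read as ChIP reads and the lower as input reads in the region, which no label or header states. Both are in lowest terms, so that the true numbers are these or a whole multiple of them. The constants were 0.39 for replicate 1, -0.0058 for replicate 2 and 0.18 for the series' list on the log2 scale. The medians of the upper and lower terms, each taken separately, were 199 and 97 in replicate 1, 189 and 125 in replicate 2 and 328 and 212 in the series' list. The median counting error of a score was at most 0.18, 0.17 and 0.13 on the log2 scale, respectively. These errors cover counting only, since reads copied by PCR are not independent molecules. Library totals are not given in the lists, so the total depth of each library is unknown.

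Covered sequence was counted base by base, with each region trimmed at the length of its scaffold in the file headers (1 region of replicate 2 and 1 of the series' list ran past an end). Replicates were compared by the Jaccard index, the bases covered in both divided by the bases covered in either. It was set against 1000 circular rotations of replicate 2 along each chromosome arm (one-sided permutation test), with 200 rotations for single chromosomes. Regions counted as shared when they overlapped by at least 1 bp. The X chromosome was compared with the autosomal arms 2L, 2R, 3L and 3R over full 500-kb windows by a two-sided permutation test with 100000 resamples, on the mean of the replicates. Neighbouring windows are not independent, so these p-values are too small. With the whole arm as the unit, 1 X against 4 autosomal arms cannot give a one-sided exact p below 0.2. Intervals for ratios of read density and for rank correlations are 95% bootstrap intervals over regions (1000 resamples). With 2 replicates of 1 group, no test between groups of samples was possible.

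Tests and settings were fixed before the data were examined, except where stated. Alternatives fixed at that stage were windows of 200 kb and 1 Mb, merging of regions closer than 1 kb for region numbers and replicate overlap, a minimum reciprocal overlap of 50%, scores above the median, the series' list and leaving out each replicate. By the rule set for named regions, these are the 10 longest and the 10 highest-scoring regions of the series' list and the 10 longest gaps between its regions on the arms 2L, 2R, 3L, 3R, X and 4. The comparison of chromosome 4 with autosomal segments, the look-up of gaps between replicates, the placement of regions at random, the score thresholds other than the median, the correlations over windows and of score with length, the recovery of read numbers, the comparison of arm ends, the common score floor, the omission of the centromere-proximal 2 Mb, the minimum width for the series' list, the merging for named regions and the read densities were chosen after seeing the data. Planned tests on gene bodies, gene features and gene lists were not run, because the gene table at hand is of release 6 and coordinates were not moved between releases. No gene is therefore named for any region.

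The programs were tested on simulated data first. In 40 simulated sets, regions with the widths of replicate 1 were placed at random with equal cover on all autosomal arms. A cover on X of 0.8 times that of the autosomes passed the window test in 100% of sets, and equal cover passed in 0%. These sets lack the clustering and the differences between arms of the real regions, so the shares are not error rates for the real data. From simulated read numbers, 100% of the pairs were recovered in lowest terms. An earlier way of finding the constant, by the smallest terms, failed this test and was replaced, which also changed the constant of replicate 1. Random scores were resolved in 0.0999% of cases. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.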

Results

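H3K27me2, a modification that Polycomb repressive complex 2 places on histone H3, was profiled by ChIP-seq in heads of wild-type adult flies to locate the sequence that carries it. The labels hold 1 group of 2 ChIP replicates, each with an input that its label assigns to the list of that replicate, and no treatment or mutant. The comparisons are therefore between chromosomes, between regions and between the replicates. Positions are 1-based on FlyBase release 5. Scores are the authors' own and, from their values, log2 ratios of whole numbers minus 1 constant per list. The upper and lower numbers are read here as ChIP and input reads, which no label or header states.

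In the replicates' lists the mark was called in many short regions spread over all chromosome arms. Replicate 1 held 10114 enriched regions over 25.9 Mb, and replicate 2 held 10115 over 25.04 Mb. On the arms 2L, 2R, 3L, 3R, X and 4 they covered 18.9% and 17.2% of the sequence, a mean of 18.1% ± 1.19 (SD, n = 2). The median region was 1972 bp long in replicate 1 and 1943 bp in replicate 2, and the shortest was 1301 bp in both. Regions over 10 kb numbered 97 and 72, and held 5.01% and 3.67% of the covered bases. The series' list held 814 such regions, with 22.5% of its covered bases, so region length depended on the list. The median score was 0.67 in replicate 1 and 0.63 in replicate 2. Longer regions scored higher within each list (Spearman's rho across regions 0.483 and 0.417, where regions are not independent replicates).

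The large autosomal arms were covered to a similar extent. Arm 2L was covered to 17.8% ± 0.0938, 2R to 22.2% ± 2.41, 3L to 21.2% ± 0.207 and 3R to 20.4% ± 0.635 (mean ± SD of the replicates, n = 2). Together these 4 arms were covered to 20.3% ± 0.636 (n = 2). The pericentric scaffolds 2RHet, 3LHet and 3RHet, which hold assembled heterochromatin next to the centromeres, had higher means of 27.3% ± 6.21, 31.4% ± 6.51 and 30.1% ± 5.35 (n = 2). Replicate 2 gave the higher cover on all of these 3 scaffolds, for example 36.0% against 26.8% on 3LHet. In replicate 1, 2RHet was covered to 22.9%, above the 4 large autosomal arms together (20.8%) but below arm 2R (23.9%). The scaffold 2LHet was covered to 15.2% ± 0.924 and XHet to 20.9% ± 0.408 (n = 2). The scaffold YHet was covered to 2.25% in replicate 1 and 7.82% in replicate 2, from 5 and 15 regions. No sequence of Uextra was listed as enriched.

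**Figure D1:**
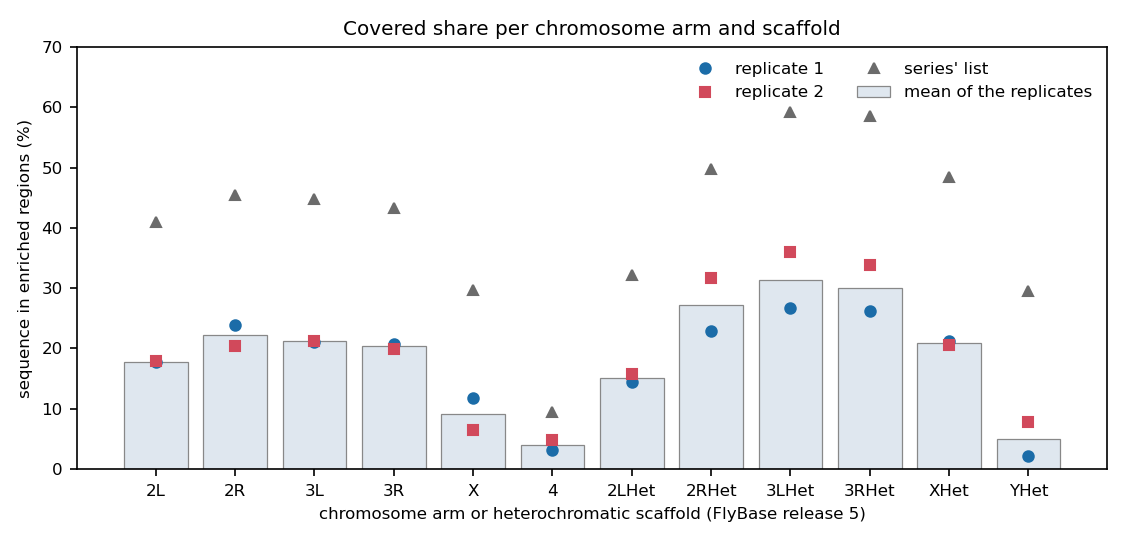
Percentage of each chromosome arm or heterochromatic scaffold (x axis) inside enriched regions (y axis), with bars for the mean of the 2 replicates, circles for replicate 1, squares for replicate 2 and triangles for the series' list. X (11.7% and 6.46%) and chromosome 4 (3.21% and 4.80%) lie below the large autosomal arms in every list.

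X, of which males carry a single copy and females a pair, was covered less than the autosomes. The share of X in enriched regions was 11.7% in replicate 1 and 6.46% in replicate 2, a mean of 9.09% ± 3.73 (SD, n = 2). Over 500-kb windows the mean cover was 8.93% on X (44 windows) and 20.4% on the autosomal arms (192 windows). The difference of -11.4 percentage points passed the permutation test (two-sided p = 1e-05, the smallest that 100000 resamples can give). X had the lowest cover of the 5 large arms, against 17.8% for the lowest autosomal arm. The replicates differed more on X than on the large autosomal arms, with 1188 regions in replicate 1 and 770 in replicate 2, against 7680 and 7731 on those arms.

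The regions that were called on X scored higher than those on the autosomes. Their median score was 0.78 against 0.65 in replicate 1 and 0.77 against 0.60 in replicate 2, higher by 0.13 and 0.17 on the log2 scale. The order of X and autosomes therefore depended on the score required. Above the median score of each list X was covered to 0.879 times the autosomal share in replicate 1, 0.576 times in replicate 2 and 1.06 times in the series' list. Above the percentile 75 the ratio was 1.29 and 1.18, and above the percentile 90 it was 1.79 and 2.74. The window difference of -11.4 percentage points shrank to -6.35 when autosomal regions below the 5th percentile of X scores were left out, and to -3.07 with regions above the median score alone (permutation p = 0.00177). With regions above the percentile 75 alone, it was 1.08 in the other direction and did not pass the test (permutation p = 0.115, a threshold chosen after seeing the data).

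**Figure D2:**
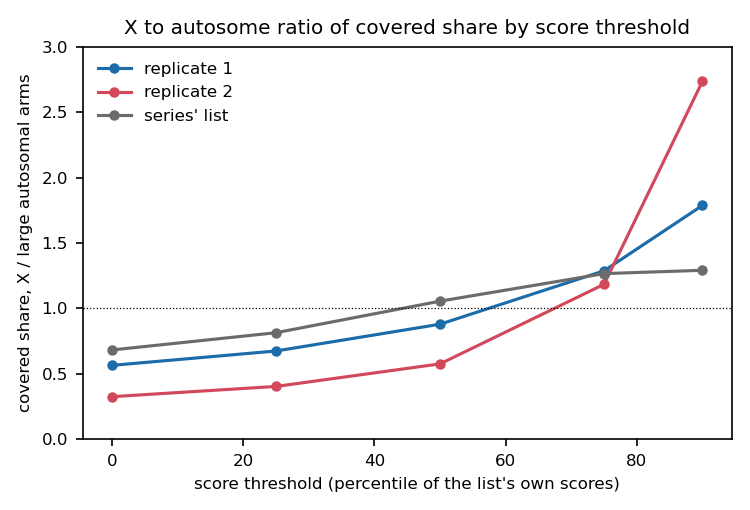
Ratio of the covered share of X to that of the large autosomal arms (y axis) when only regions above a percentile of their own list's scores (x axis) are kept, for both replicates and the series' list. Without a threshold the ratios are 0.564, 0.325 and 0.682, and at the percentile 75 all 3 lie above the dotted line at 1.

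Chromosome 4, the small dot chromosome known for its heterochromatin-like packaging, had the lowest cover of all arms. It held 18 regions in replicate 1 and 29 in replicate 2, which covered 3.21% and 4.80% of its 1.35 Mb, a mean of 4.00% ± 1.12 (SD, n = 2). Autosomal segments of the same length, taken every 100 kb along the large arms, had a median cover of 19.9%. None of the 913 segments was covered as little as chromosome 4, and the lowest reached 8.04%, at 15200001 to 16551857 on 2L. Segments overlap and come from 4 arms, so this count is a description and no p-value was computed. The regions of chromosome 4 had median scores of 0.56 and 0.57, against autosomal medians of 0.65 and 0.60. The 95% bootstrap intervals of these differences, -0.16 to 0.0071 and -0.080 to 0.012, include 0.

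The longest stretches without enrichment lay at a few sites on the arms. In the series' list the longest gap was 418260 bp on 3R, from 2471921 to 2890180, and the next was 388370 bp on the same arm, from 12450647 to 12839016. Arm 3R also held the gaps from 6203589 to 6501759 (298171 bp) and from 17163164 to 17398518 (235355 bp). The others among the 10 longest lay on X from 4264071 to 4523391, on 4 from 346577 to 572593, on 2L from 11284028 to 11499312, on 2R from 7335224 to 7540507, and on 3L from 6756693 to 6958205 and from 12565388 to 12766803. The replicates covered at most 0.461% of any of these 10 gaps on average, and 5 of the gaps touched no region of either replicate. This follows largely from the choice of gaps, since the series' list contains 96.6% and 98.5% of the replicates' covered bases. The median gap on the arms was 1301 bp, and 48 gaps exceeded 100 kb. When the same regions were placed at random 100 times, the longest gap on any arm had a median of 103 kb and never exceeded 188 kb. Random placement does not keep the clustering of the real regions, so this comparison shows only that they are not scattered at random.

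**Figure D3:**
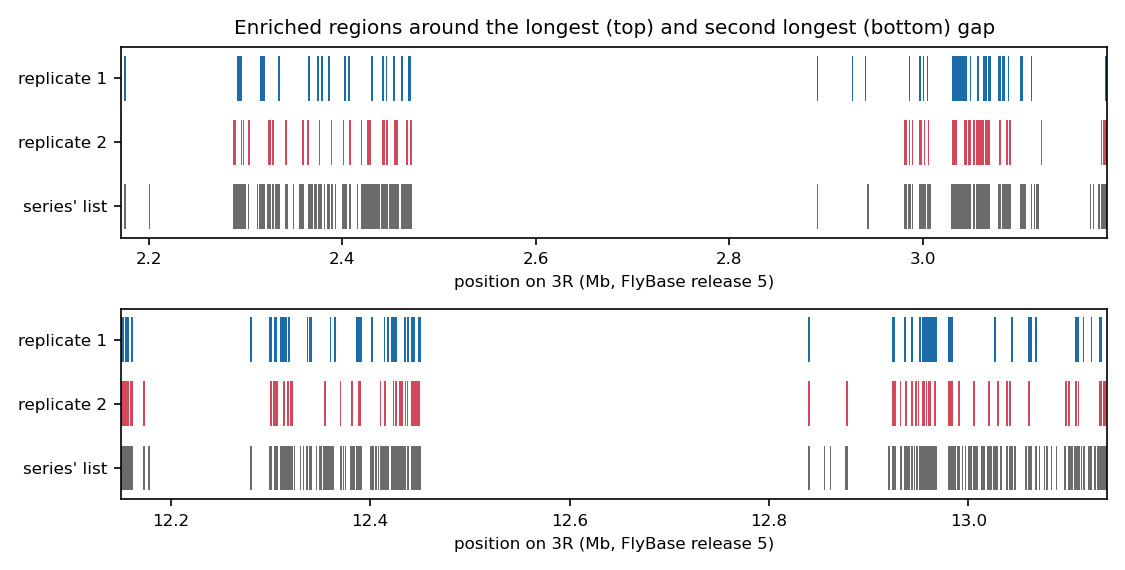
Enriched regions of replicate 1, replicate 2 and the series' list (rows of bars) along 3R in Mb around the longest gap (top, 2471921 to 2890180) and the next longest (bottom, 12450647 to 12839016). Replicate 1 covers 0.0325% of the first gap and replicate 2 covers 0.0144% of the second, and neither covers any of the other.

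The gaps recurred between replicates. The 10 longest gaps of replicate 1 on the large autosomal arms (209.6 to 419 kb, 2788 kb together) were covered to 0.790% in replicate 2, against a mean of 19.0% after rotation of replicate 2 along the arms. The 10 longest gaps of replicate 2 (207 to 509 kb) were covered to 1.53% in replicate 1, against 20.6% after rotation. Both values lay below all 10000 rotations (one-sided permutation p = 0.0001 each, the smallest they can give). The lists do not record where reads could be aligned, so a gap is sequence without a call.

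The longest enriched regions were on 3R, 3L and 2L. The longest region of the series' list spanned 108653 bp on 3R, from 27288888 to 27397540, with a score of 0.66. Replicates 1 and 2 covered 78.9% and 79.1% of it, each with 18 separate regions. The next were a region of 64941 bp on 3L (6257841 to 6322781), covered to 65.1% ± 7.68, and one of 64710 bp on 2L (22578853 to 22643562), covered to 70.3% ± 6.35 (mean ± SD, n = 2). The region from 25077643 to 25139041 on 3R had the highest replicate cover of the 10, with 91.0% ± 4.66 (n = 2) and a score of 0.81. All 10 had regions in both replicates, and their mean cover ran from 54.0% to 91.0%. The lowest of these, 27764346 to 27810641 on 3R, was covered to 29.8% in replicate 1 and 78.1% in replicate 2, so its mean rests on replicate 2.

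The highest-scoring regions were of another kind. The 10 highest scores of the series' list, 3.14 to 4.28, belonged to regions of 1003 to 2420 bp. Unplaced sequence U held 6 of them, 3L held 2, and 2RHet and 3RHet held 1 each. The top score was at 1656373 to 1658391 on 3RHet, with terms in the ratio of 22 to 1. All 10 ratios had an input term of 1 or 2 and a ChIP term between 10 and 25. Their counting errors were between 1.06 and 1.51 on the log2 scale if the terms are the read numbers. In the replicates, 9 of the 10 overlapped no region, and the other, on U, overlapped 1 region of replicate 2. Most of the 10 were shorter than 1301 bp, the shortest region in either replicate. The replicates' lists thus held no region that short, which may be part of the missing overlap.

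**Figure D4:**
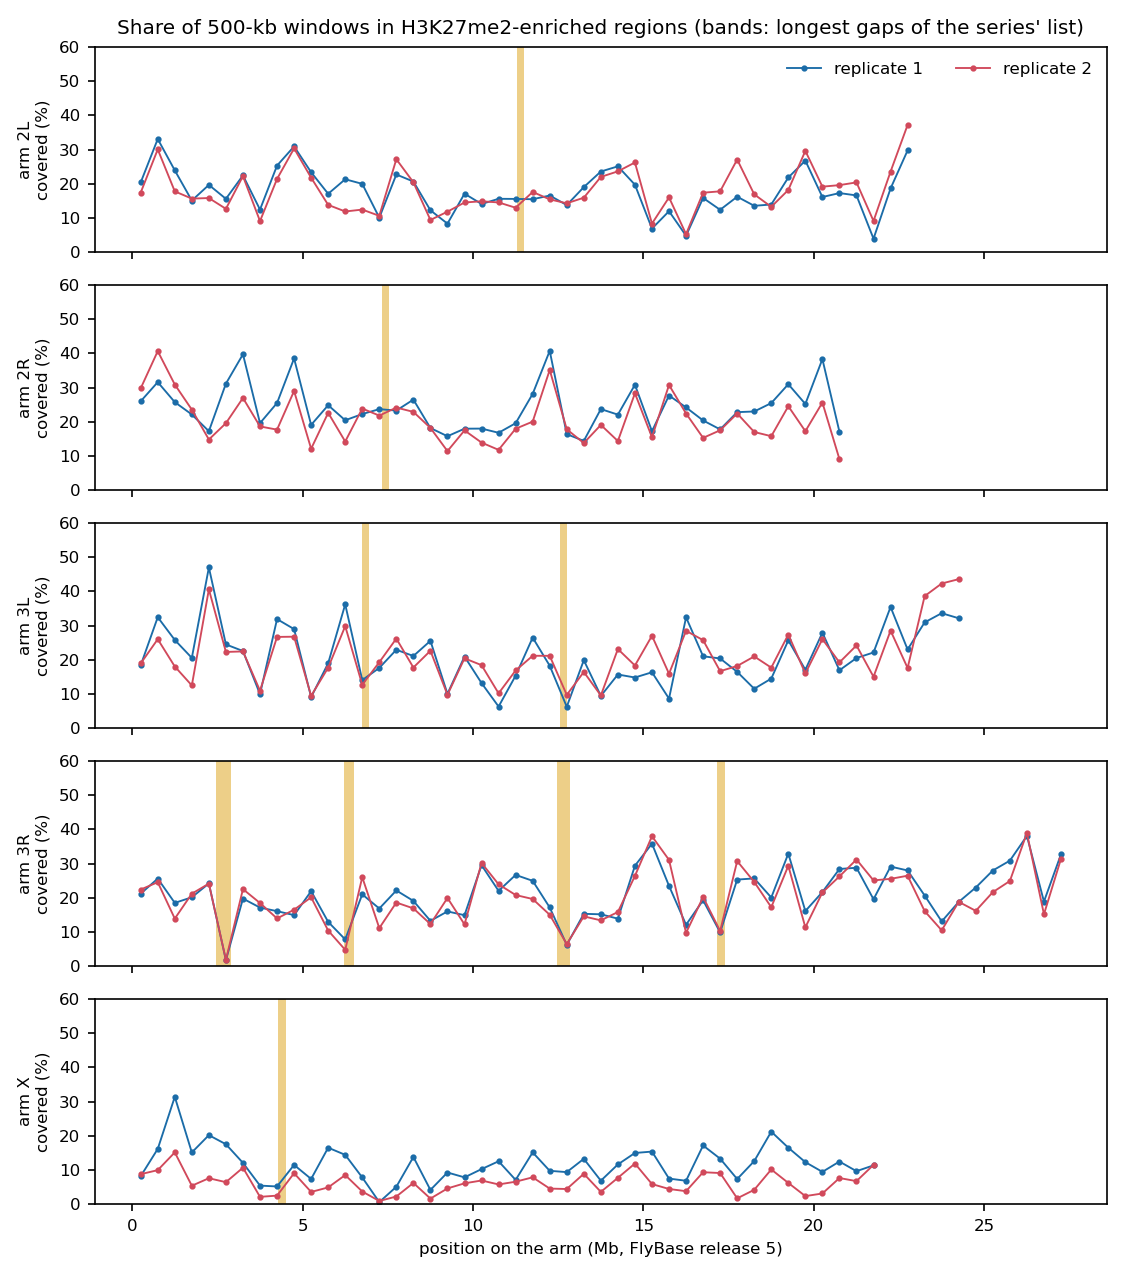
Percentage of each full 500-kb window inside enriched regions (y axis) along the 5 large arms in Mb (x axis) for replicate 1 and replicate 2, with bands at the longest gaps of the series' list. Cover correlates between the replicates with a Pearson r of 0.825 on the autosomal arms, and replicate 2 lies below replicate 1 in 41 of the 44 windows of X.

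The replicates overlapped more than rotated copies of each other. The Jaccard index on the arms was 0.340, against a mean of 0.107 and a maximum of 0.137 in 1000 rotations (one-sided permutation p = 0.001, the smallest they can give). It was 0.363 on the large autosomal arms, 0.312 on chromosome 4 and 0.154 on X. X had the lowest rotated mean of the large arms, 0.0434, and its index was 3.55 times that mean, against 3.19 times for the large autosomal arms. The largest index in 200 rotations was 0.143 on X and 0.302 on chromosome 4, each close to the observed index. On the large autosomal arms it was 0.124. At least 1 bp was shared by 62.7% of the regions of replicate 1 (6341 of 10114) and by 63.5% of those of replicate 2 (6427 of 10115). On X the shares were 33.2% and 52.2%. Cover per 500-kb window correlated between replicates with a Pearson r of 0.825 over 192 autosomal windows and 0.729 over 44 windows of X, where windows are not independent replicates. Across 6341 pairs of overlapping regions, scores correlated with a Spearman's rho of 0.441 (95% bootstrap interval 0.421 to 0.462) and a Pearson r of 0.530. Within the autosomal arms rho was 0.308 (4980 pairs) and within X 0.234 (394 pairs), both below the value over all pairs.

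The series' list was wider than either replicate. It held 16728 regions over 56.9 Mb and covered 40.6% of the arms, with a shortest region of 1001 bp. It contained 96.6% of the covered bases of replicate 1 and 98.5% of those of replicate 2. Of its own bases on the arms, 22.6% lay in both replicates, 41.5% in 1 and 35.9% in neither. Of its regions, 4638 (27.7%) touched both replicates, 5512 (33.0%) touched 1 and 6578 (39.3%) touched neither. Regions in both had a median length of 5325 bp and a median score of 0.54, and those in neither 1378 bp and 0.43. The order of the chromosomes was kept for the groups compared above, with 43.6% on the large autosomal arms, 29.7% on X and 9.49% on chromosome 4.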

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

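The tests of explanations in this part were chosen after the results were seen. Enriched regions also lay on unplaced sequence U, which the comparisons of covered share in the main results left out, although counts over whole lists include it. There were 430 in replicate 1 and 592 in replicate 2, with median scores of 0.90 and 0.82. No explanation was tested for them.

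X was covered to 0.564 times the autosomal share in replicate 1 and 0.325 times in replicate 2. A fixed score floor at the 5th percentile of X scores did not account for the whole difference. With autosomal regions below that floor left out, the ratio was still 0.677 in replicate 1 and 0.489 in replicate 2 (mean 0.583). A higher floor was not argued against. Autosomal regions at or above the percentile 75 of their list (scores of 0.770 and 0.712) covered 5.76% and 4.16% of the autosomal arms. That is less than the 11.7% and 6.46% of X that all X regions covered, although many X regions scored below these thresholds. A candidate explanation is thinner reads on X: the 75th percentile of input reads per kb in X regions was on average 0.590 times the autosomal one. This ratio was lower in replicate 2, the replicate with less cover, by a difference of -0.119 (95% interval -0.140 to -0.102). The interval is over regions, each list having its own, and does not measure the spread between replicates. Whether thin reads raise the scores of X regions was not decided, since the mean ratio of cover above the median score, 0.727, follows from the higher scores on X themselves. Lower H3K27me2 on X stays open, no biological explanation was tested, and the sex ratio of the flies (an input ratio of 0.5 for males, 0.75 for an equal mix, 1 for females) is not in the labels.

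Chromosome 4 was covered to 0.155 and 0.241 times the autosomal share in the replicates and 0.218 times in the series' list. A fixed score floor as the whole cause was argued against, since the mean ratio was 0.245 when autosomal regions below the median of chromosome 4 scores were left out, which lowered the autosomal cover from 20.8% to 18.4% in replicate 1 and from 19.9% to 15.3% in replicate 2. For thin reads, the 75th percentile of input density in its regions was on average 1.08 times the autosomal one, and 1.19 times in the series' list (95% interval 1.04 to 1.28, 48 regions, against 0.598 for X), which goes against them, as does replicate 2 (0.936 to 1.26). They were not excluded, since the interval of replicate 1 (0.628 to 1.34, 18 regions) reaches below the ratio of X, 0.650, and the ratios at the median were 0.722, 0.943 and 0.922 in replicate 1, replicate 2 and the series' list. Sequence without alignable reads stays open as well, because only called regions have read numbers, and no biological explanation was tested.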

How the results depend on the processing

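No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, have no values of their own here. Tests on gene lists and gene features, fixed beforehand, were not run, for want of an annotation of the files' release. The score floor, the omission of the proximal 2 Mb, the percentile 75 of scores, the minimum width for the series' list, the merging for named regions and the settings for chromosome 4 were added after seeing the data. The window difference between X and the autosomes kept its direction and passed the test with 200-kb and 1-Mb windows, the series' list and the omission of the proximal 2 Mb. It kept both at a smaller size with the score floor (-6.35) and with scores above the median in the replicates (-3.07), where the ratio of cover in the series' list was 1.06. It ranged from -13.7 to -9.18 percentage points when 1 replicate was left out. It turned to 1.08 above the percentile 75 of scores, and the cause was not tested. The Jaccard index passed its test above the median score (0.256) and after merging (0.354). A reciprocal overlap of 50% moved the shared regions from 63.1% to 32.7% and the rank correlation of scores from 0.441 to 0.581, over fewer pairs. The share of the series' regions found in both replicates moved from 27.7% to 13.7% when each replicate had to cover 50% of the region, and to 34.6% among regions of at least 1301 bp, where short regions leave the denominator. Scores above the median keep, by construction, 5058 regions per replicate, which covered 10.4% of the arms. Chromosome 4 was covered to 9.49% in the series' list and to 3.21% to 4.80% with 1 replicate left out, and 0 of 913 autosomal segments was as low in each of these settings. Leaving out a replicate gave 10114 to 10115 regions and a cover of 17.2% to 18.9%. How the size of the lists was set is not given, so the near-equal numbers are no evidence of stability. Merging moved the cover of 4 of the 10 longest regions by more than the spread between replicates, the longest from 79.0% to 83.2%. Library totals are unknown, and scores of regions with few input reads carry counting errors above 1 on the log2 scale.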

Other observations

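The tests in this part were chosen after the results were seen. Cover near the centromeres differed between arms. In the centromere-proximal 2 Mb, mean cover of the replicates was 32.8% on 3L against 20.1% on the rest of the arm, and 28.8% on 2R against 21.5%. On 3R it was 20.9% against 20.3%. On 2L and X the replicates ran in opposite directions, with 17.1% against 17.8% on 2L and 11.65% against 11.74% on X in replicate 1, and 22.3% against 17.4% and 10.5% against 6.06% in replicate 2. The mean difference over the 5 arms was 2.47 percentage points in replicate 1 (higher in the proximal part on 3 of 5 arms) and 7.47 in replicate 2 (5 of 5 arms), 4.97 on average. An exact sign-flip test over arms, on the mean of the replicates, gave a two-sided p of 0.0625, the smallest that 5 arms allow.

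The number of regions was 10114 in replicate 1 and 10115 in replicate 2, although their chromosome make-up differed. The shortest region was 1301 bp in both replicates and 1001 bp in the series' list.

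The series' list may have been called on the pooled reads of both replicates. The comparison below assumes that each scaling ratio is the ratio of ChIP to input library totals, which was not tested. Under pooling, the scaling ratio of the series' list (1.14) must then lie between those of replicate 1 (1.31) and replicate 2 (0.996). Its place between them is set by the share of replicate 1 in the input. That share was 44.6% from the scaling ratios and 43.3% from the input reads per kb in autosomal regions, a difference of 1.29 percentage points. The same percentile was 169.6 reads per kb in the series' list, against a sum of 166 for the replicates. Each list has its own regions and the terms are in lowest terms, so these values are not overall depths. Pooled reads would also make shorter and weaker regions callable, but a different threshold for the series' list was not excluded.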
